A study of mouse gut metagenome with 10 samples.

How the data were processed

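The bacterial community of the stomach was profiled in 10 male C57BL/6 mice by sequencing part of the 16S rRNA gene, a marker present in all bacteria whose sequence differs between taxa. Per the labels' protocols, DNA was extracted from the gastric flora, the V3 and V4 regions were amplified by PCR, and the products were sequenced on an Illumina MiSeq. The authors deposited a table of raw read counts per operational taxonomic unit (OTU, a cluster of near-identical reads), with a taxonomy string for each OTU. Trimmomatic, a read trimmer, is named in the submitters' processing notes. The clustering method, its identity threshold, any chimera filter and the taxonomy database are not given in the sources used here. Names in square brackets, such as [Ruminococcus] and [Prevotella], are kept as the table gives them and are separate from the unbracketed genera.

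The table held 4038 OTUs, of which 1573 had no read in any of the 10 mice and 721 had exactly 1. All 10 count columns matched a sample by its label, and 0 were left over. Library totals ran from 22438 to 28578 reads. The 22 OTUs named as plastid or mitochondrion and the 11 with no phylum were left out of the shares and took 0.517% ± 0.774 (SD, n = 10) and 0.0426% ± 0.0659 (SD, n = 10) of all reads, or 0.283% and 0.0224% without mouse 1. Shares are percentages of the remaining reads, 22266 to 28421 per library, and each mouse was weighted equally. A share given for a single mouse carries a 95% exact Clopper-Pearson interval, or falls within the general bound that follows. Over all taxa tabulated, the largest half-width of such an interval was 0.635 percentage points, 0.377 points for shares up to 10% and 0.127 points for shares up to 1%. A taxon with 0 reads in a library could have a share of up to 0.0106% to 0.0135%, the value of 3 counts, near a one-sided 95% limit. The two-sided exact interval for 0 reads is wider and ends at 0.0130% to 0.0166%. PCR reads without molecular identifiers are not independent molecules, so intervals and limits cover counting error only.

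All 10 mice had the same diet label, so no groups were compared. Before the data were examined, the tests, the taxa to be named, 13 lists of taxa and the alternative settings were chosen. The text names each phylum with a mean share of at least 1%, the 10 leading families, 15 leading genera and 10 leading OTUs. It also names each list member with a mean share of at least 0.1% or reads in at least 8 mice, up to 5 called pairs of genera in each direction, and any mouse set apart by Dixon's test. Other taxa named in the closing section were chosen after their values were seen. The list Muribaculaceae was matched by the table's family name S24-7, an older name of the same family.

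Within-mouse differences in share were tested with an exact two-sided sign-flip permutation test over 6 comparisons, whose smallest possible p with 10 mice is 0.00195. The 95% interval of a mean difference holds the shifts that this test did not reject. Relations across mice were tested with Pearson's r and Spearman's rho, two-sided, by a permutation test with 100000 resamples, over 8 relations. Relations between taxa used centred log ratios with 0.5 added to each count. Genus reads were compared over libraries with a chi-square test for genera with a mean share of at least 0.1%. Bray-Curtis dissimilarity was set against 1000 sets of multinomial draws from the mean of the mice's shares, at the same depths. The plan named the pooled profile, and the mean was used so that each mouse had equal weight. Pairs of those genera with reads in at least 8 mice were tested with Spearman's rho on centred log ratios, two-sided, by a permutation test with 100000 resamples, with 100 shuffles for the number expected by chance. All adjusted p-values are Benjamini-Hochberg values within their family, with a threshold of 0.05. Shannon diversity uses the natural logarithm, and richness was also computed after rarefying to the smallest library in 100 draws.

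Each pair of libraries was checked for duplication with a chi-square test over OTUs with at least 10 reads in the pair. The statistic per degree of freedom was between 12.3 and 87.5, so no 2 libraries agreed within sampling noise. No cage, extraction or sequencing batch is labelled, so no value within a batch was computed.

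The tests were run on simulated data first. With 31 genera, the chi-square test recovered 83% of genera that varied with a log SD of 0.2 and 99% at 0.5. In simulations with no change it called 0.323% of them. The test of genus pairs recovered 2% of pairs simulated at a correlation of 0.9 and 40% at 0.98, so few pairs can be called with 10 mice. The sign-flip test gave p under 0.05 in 5.65% of simulations without a difference. The alternatives were rarefying, keeping all OTUs, leaving out OTUs under 10 reads, leaving out each mouse, and other measures, pseudocounts and minimum shares. Merging OTUs that tracked each other was added after the data were seen. The work used Python 3.11.15, pandas 2.3.3, NumPy 2.4.6, SciPy 1.17.1 and Matplotlib 3.10.9.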

Results

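The stomach bacteria of 10 male C57BL/6 mice were profiled by 16S rRNA gene sequencing. Their labelled age is 6 to 8 weeks, and the labels do not say at which point of the experiment. The mice had eaten a diet with 5% NaCl for 4 weeks and then a normal-salt diet for 4 weeks, with sterile feed. Feeding for 4 and then 4 weeks leaves no time before it at the labelled age, so that age can hardly be the age at sampling. All 10 mice form 1 group. No sample on another diet was analysed here, so the values describe this group and do not measure an effect of salt. Libraries held 24883 ± 1892 reads (SD, n = 10), between 22438 and 28578.

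The gastric community was made up mainly of Firmicutes, the phylum of lactobacilli and clostridia, and Bacteroidetes, a phylum of polysaccharide-degrading gut anaerobes. Firmicutes held 69.1% ± 10.9 (SD, n = 10) of bacterial reads and Bacteroidetes 25% ± 10.5 (SD, n = 10). Proteobacteria held 3.14% ± 2.65 (SD, n = 10) and Actinobacteria 1.10% ± 1.09 (SD, n = 10). Reads were named for 17 phyla, of which 7 had reads in all 10 mice.

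Lactobacillaceae was the leading family on average, at 22.6% ± 15 (SD, n = 10), and all of its reads were named Lactobacillus, a lactic acid producer that colonises the mouse forestomach. S24-7 (Muribaculaceae), a leading Bacteroidales family of the mouse gut, followed at 20.5% ± 11.4 (SD, n = 10). By median the order was reversed, with S24-7 at 19.6% and Lactobacillaceae at 15.5%. Lachnospiraceae and Ruminococcaceae, anaerobic fermenters with many butyrate producers, held 13.3% ± 4.75 and 7.55% ± 2.29 (SD, n = 10 each). Clostridiales with no family name held a further 22.5% ± 11.6 (SD, n = 10). S24-7 had the highest share of the named families in 5 mice, Lactobacillaceae in 4 and Lachnospiraceae in 1.

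The other leading families were minor. Bacteroidaceae held 2.46% ± 1.27 and Clostridiaceae 1.49% ± 1.95 (SD, n = 10 each), or 0.931% for Clostridiaceae without mouse 4. Enterobacteriaceae, facultative anaerobes, held 0.986% ± 0.985 (SD, n = 10), with Escherichia at 0.417% ± 0.372. Bifidobacteriaceae held 0.919% ± 1.05, Erysipelotrichaceae 0.778% ± 0.852 and Brucellaceae 0.691% ± 0.971 (SD, n = 10 each). Without mouse 1, Bifidobacteriaceae held 0.598% and Brucellaceae 0.394%.

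**Figure D1:**
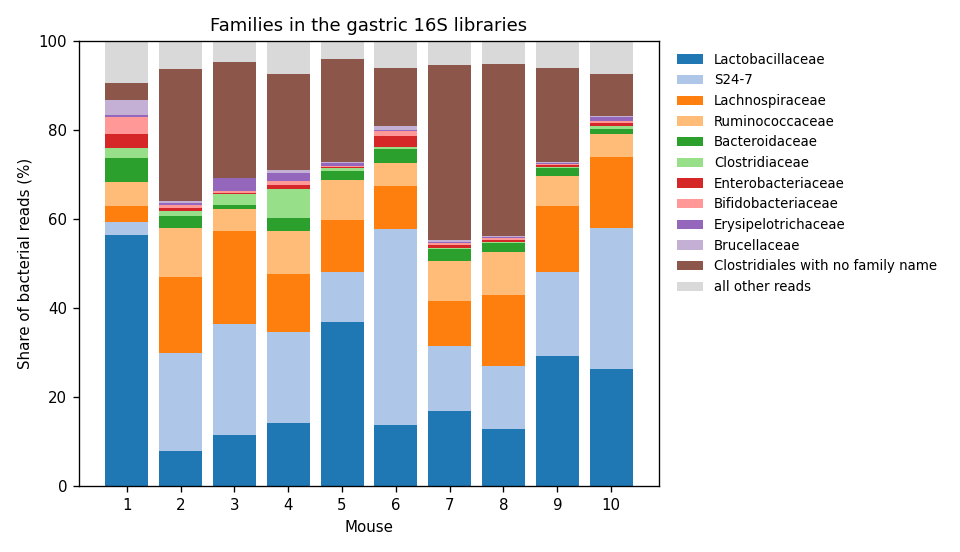
Stacked bars give the share of bacterial reads (%) of the 10 leading families, of Clostridiales with no family name and of all other reads in each of the 10 mice. Lactobacillaceae reached 56.5% in mouse 1, and S24-7 reached 44.0% in mouse 6.

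Single mice lay far from these means. The Lactobacillus share ran from 7.98% (95% exact interval 7.63 to 8.34%) in mouse 2 to 56.5% (95% exact interval 55.9 to 57.1%) in mouse 1. The S24-7 share ran from 2.88% (95% exact interval 2.68 to 3.10%) in mouse 1 to 44.0% (95% exact interval 43.3 to 44.6%) in mouse 6. Mouse 6 was the 1 mouse with more Bacteroidetes than Firmicutes reads, at 48.9% (95% exact interval 48.3 to 49.5%) and 43.9% (95% exact interval 43.3 to 44.5%).

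Below the family, Clostridia genera followed Lactobacillus. [Ruminococcus], whose reads were nearly all named gnavus, a mucin-degrading species, held 3.25% ± 3.17 (SD, n = 10). Oscillospira held 2.79% ± 1.37, Ruminococcus, a genus with fibre-degrading species, 2.54% ± 1.10, and Coprococcus 1.5% ± 1.22 (SD, n = 10 each). Roseburia and Faecalibacterium, both butyrate producers, held 0.852% ± 0.692 and 0.549% ± 0.804 (SD, n = 10 each), or 0.301% for Faecalibacterium without mouse 1. Among Bacteroidales, Bacteroides held 2.46% ± 1.27, Prevotella 0.625% ± 0.374 and [Prevotella] 0.493% ± 0.20 (SD, n = 10 each). Mucispirillum, which lives in intestinal mucus, held 0.462% ± 0.40 (SD, n = 10), and Ochrobactrum, an environmental genus, 0.690% ± 0.969 (SD, n = 10), or 0.393% without mouse 1. Allobaculum held 0.505% ± 0.834 (SD, n = 10) and had reads in 9 of 10 mice, with 0 reads in mouse 6, which allows a share of up to 0.0125%. Without mouse 3 its mean was 0.299%.

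**Figure D2:**
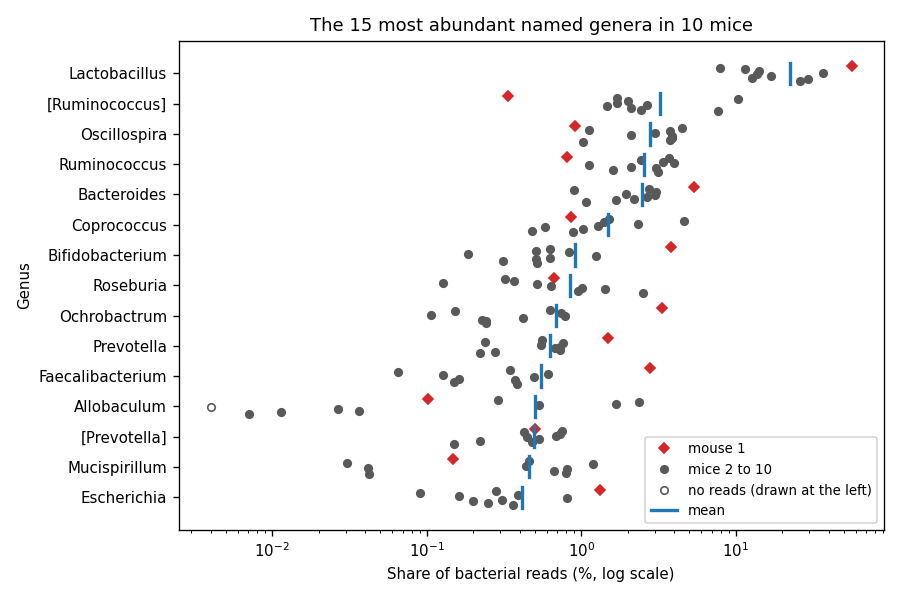
Points give the share of bacterial reads (%, log scale) of the 15 most abundant named genera in each of 10 mice, with mouse 1 as red diamonds and the mean as a blue line. Lactobacillus lies above every other genus on average, and the open point marks mouse 6, with 0 Allobaculum reads.

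The lists of taxa fixed beforehand differed widely in share. Lactic acid bacteria held 22.7% ± 15 (SD, n = 10), with reads in 3 of 9 listed genera. Lactobacillus made up nearly all of it, and Streptococcus held 0.150% ± 0.173 (SD, n = 10), or 0.0992% without mouse 6. Clostridia fermenters held 20.8% ± 5.58 (SD, n = 10), with reads in 4 of 6 listed families, of which Christensenellaceae held 0.0244% ± 0.0193. Bacteroidales genera outside S24-7 held 3.35% ± 1.77 (SD, n = 10), with reads in 4 of 8, and Parabacteroides held 0.262% ± 0.196 of the reads. Bifidobacterium, a carbohydrate fermenter, held 0.918% ± 1.05 and Akkermansia, a mucin user, 0.396% ± 0.434, together 1.31% ± 1.04 (SD, n = 10 each). Bifidobacterium held 0.597% without mouse 1. Desulfovibrionaceae, a family of sulfate reducers, held 0.259% ± 0.162 (SD, n = 10).

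Some listed bacteria were scarce or not detected. Helicobacter, the genus with gastric pathogens, had 0 of 247398 reads named to it over the libraries. Its family, Helicobacteraceae, had 35 reads in 5 mice with no genus name, a mean share of 0.0146% (0.00942% without mouse 3), so the genus cannot be bounded below that. Segmented filamentous bacteria, ileal commensals that attach to the epithelium, also had 0 reads named to them. Only 45.4% ± 16.4 (SD, n = 10) of reads carried a genus name, so their share among the other reads is not bounded. Salt-tolerant skin and food genera held 0.0594% ± 0.0467 (SD, n = 10), with reads in 6 of 9 listed genera, and Corynebacterium held 0.0358% ± 0.0233 of the reads.

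The listed genera often found in DNA kits and water held 0.461% ± 0.390 (SD, n = 10), with reads in 10 of 17 listed genera. Environmental genera outside the list are not in this sum, so it does not measure all background. Ochrobactrum, one of them, held 0.690% ± 0.969 (SD, n = 10), or 0.393% without mouse 1. Stenotrophomonas held 0.231% ± 0.183, Sphingomonas 0.0693% ± 0.0774 and Acinetobacter 0.0558% ± 0.0803 (SD, n = 10 each). Methylobacterium held 0.0379% ± 0.0593 and Comamonas 0.0341% ± 0.0584 (SD, n = 10 each). Without mouse 1 the means of Sphingomonas, Acinetobacter, Methylobacterium and Comamonas were 0.0461%, 0.035%, 0.0194% and 0.0175%.

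The 10 leading OTUs held 39.8% ± 6.54 (SD, n = 10) of reads. OTU1212, a Lactobacillus, held 8.00% ± 5.29, OTU1571, of S24-7, 6.48% ± 6.55, and OTU1962, a Lactobacillus, 4.59% ± 5.44 (SD, n = 10 each). OTU352, named Lactobacillus reuteri, a species of rodent and human guts, held 4.42% ± 4.42, and OTU678, also of Lactobacillus, 2.35% ± 2.94 (SD, n = 10 each), or 1.56% for OTU678 without mouse 5. OTU3803, of S24-7, held 3.42% ± 2.98 (SD, n = 10). The clostridial OTUs among them were OTU3520 at 3.02% ± 2.17, OTU3824 at 2.81% ± 3.19, OTU1347, of Lachnospiraceae, at 2.44% ± 2.49 and OTU2433 at 2.30% ± 2.59 (SD, n = 10 each). The most abundant Lactobacillus OTU was OTU1212 in 6 mice, OTU352 in 3 and OTU1962 in 1. Within S24-7 it was OTU1571 in 6 mice and OTU3803 in 4.

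A shared set of OTUs held most of the reads in every mouse. The 164 OTUs with reads in all 10 mice held 76.6% ± 6.30 (SD, n = 10) of them. They comprised 103 Firmicutes, of which 85 were Clostridiales and 17 Lactobacillales, 42 Bacteroidetes, 13 Proteobacteria and 3 Actinobacteria. Deferribacteres, TM7 and Verrucomicrobia each gave 1. Another 989 OTUs, 40.5% of those with reads, were seen in 1 mouse and held 1.0% of reads on average. The shared number fell to 80 when at least 3 reads were asked for in each mouse.

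Firmicutes exceeded Bacteroidetes within mice, by 44.1 percentage points ± 21.2 (SD, n = 10), in 9 of 10 mice. The exact sign-flip permutation test gave p = 0.00391, adjusted p = 0.0117 over 6 comparisons. Lachnospiraceae exceeded Ruminococcaceae by 5.71 points ± 4.96 (SD, n = 10), in 9 of 10 mice, with mouse 1 as the exception (exact p = 0.00586, adjusted p = 0.0117). Clostridiales with no family name, which may hold members of either family, are not in this comparison. Proteobacteria held less than Bacteroidetes in all 10 mice, with a mean difference of -21.9 points ± 10.9 (SD, n = 10). Its exact p of 0.00195, the smallest that 10 mice can give, became 0.0117 after adjustment.

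Lactobacillus, S24-7 and the Clostridia fermenters differed by less than the spread between mice. The Clostridia fermenters are named families only. They leave out Clostridiales with no family name, at 22.5% ± 11.6 (SD, n = 10), so they do not stand for all clostridia. Lactobacillus minus S24-7 was 2.09 points ± 23.5 (SD, n = 10), with a 95% interval of -13.8 to 19.5 points. Lactobacillus was higher in 4 of 10 mice (exact p = 0.803, adjusted p = 0.945). Lactobacillus minus Clostridia fermenters was 1.76 points ± 19.5 (SD, n = 10), interval -10.8 to 16.6 points, higher in 4 of 10 mice (exact p = 0.826, adjusted p = 0.945). Clostridia fermenters minus S24-7 was 0.331 points ± 11.9 (SD, n = 10), interval -8.52 to 7.12 points, higher in 8 of 10 mice (exact p = 0.945, adjusted p = 0.945). The sign of each mean rested on single mice. Without mouse 1 the means were -3.63, -3.33 and -0.302 points. Lactobacillus minus S24-7 was -0.517 points without mouse 5, and Clostridia fermenters minus S24-7 was -0.299, -0.670, -0.143 and -0.872 points without mouse 2, 5, 7 or 8.

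**Figure D3:**
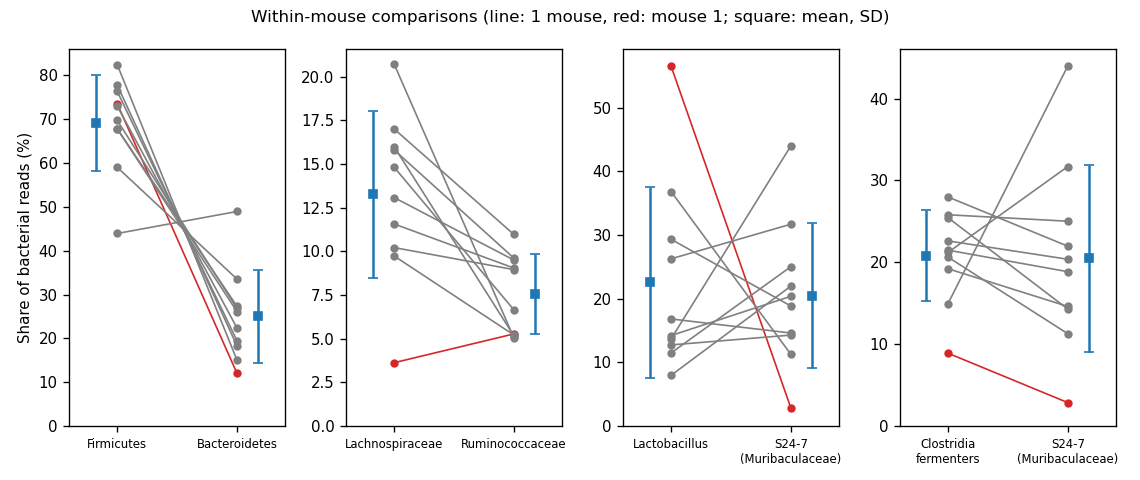
Each line joins the shares of bacterial reads (%) of 2 taxa in 1 mouse, with mouse 1 in red, and squares with bars give the mean and SD over 10 mice. Firmicutes lie above Bacteroidetes and Lachnospiraceae above Ruminococcaceae in 9 of 10 mice each, while the lines of Lactobacillus and S24-7 cross.

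The libraries held 842 ± 113 observed OTUs (SD, n = 10), from 657 in mouse 1 to 1017 in mouse 7, and 811 ± 105 after rarefying. Chao1, an estimate of total richness, was 1235 ± 198 (SD, n = 10). Shannon diversity was 4.49 ± 0.338 (SD, n = 10), from 3.87 in mouse 1 to 4.91 in mouse 8, and the inverse Simpson index was 30.6 ± 12.9 (SD, n = 10). Good's coverage was 98.8% ± 0.174 (SD, n = 10). Over genera in place of OTUs, mean Shannon diversity was 2.27.

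Mean Bray-Curtis dissimilarity over the 45 pairs of mice was 0.544 ± 0.121 (SD over pairs), against a mean of 0.0772 and a highest value of 0.0801 in multinomial draws. The draws hold read sampling alone, which separate animals exceed almost by construction, so no p-value is given. Mice 2 and 4 were closest, at 0.252, and mice 1 and 2 farthest, at 0.765. Unlabelled cage or processing is not separated here from differences between mice.

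**Figure D4:**
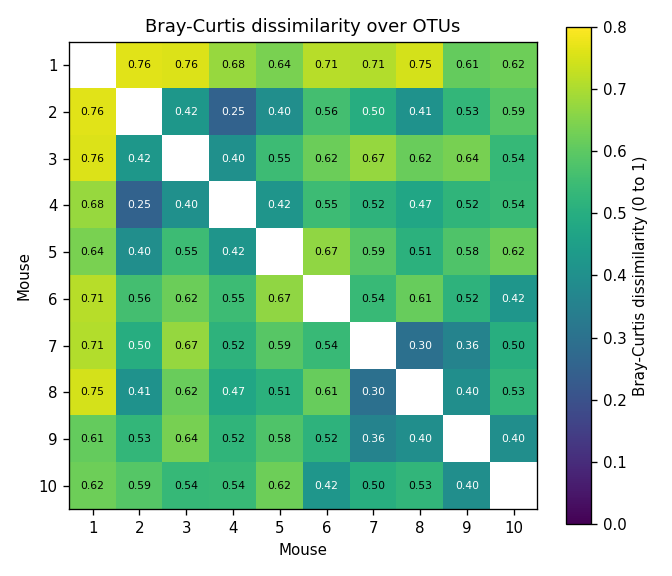
Each cell gives the Bray-Curtis dissimilarity (0 to 1) over OTUs between 2 of the 10 mice. Mouse 1 has the highest mean dissimilarity to the others, at 0.694, and the pair of mice 2 and 4 has the lowest, at 0.252.

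The spread of genera between mice differed widely. For the 31 genera with a mean share of at least 0.1%, the between-mouse coefficient of variation ran from 38.7% for Clostridium to 165% for Allobaculum. Its median was 94.6%, against 10.4% from counting error alone. All 31 passed the chi-square test after adjustment over 31 genera, but that test treats reads as independent and covers counting error only, so separate mice were bound to pass it. Of these genera, 29 had reads in all 10 mice, and 10 were highest in mouse 1.

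The relation of Lactobacillus share to Shannon diversity did not pass adjustment over 8 relations with all 10 mice. Pearson's r was -0.775 (permutation p = 0.00635, adjusted p = 0.0508) and Spearman's rho -0.661 (permutation p = 0.0438, adjusted p = 0.175). Without mice 1 and 5, the farthest in Lactobacillus share, r was -0.381, so the size of r depended on those mice. Leaving them out also narrows the range of shares, which can shrink r. With any single mouse left out, rho stayed between -0.783 and -0.533. Shannon diversity is computed from the same reads, so a high share of 1 genus can lower it by arithmetic, and the 2 measures are not independent. Without mouse 3, 6, 9 or 10, r passed the threshold, at -0.818, -0.877, -0.799 and -0.778 (exact permutation test, adjusted p = 0.0359, 0.0234, 0.0485 and 0.0464), while rho did not. Lactobacillus and S24-7 on the log-ratio scale gave r = -0.467 (permutation p = 0.172, adjusted p = 0.458) and rho = -0.333 (permutation p = 0.35, adjusted p = 0.560), and r was 0.301 without mice 1 and 5. Lactobacillus and Clostridia fermenters gave r = -0.257 (permutation p = 0.480, adjusted p = 0.549) and rho = -0.0788 (permutation p = 0.838, adjusted p = 0.838), and r was 0.246 without those mice. That rho turned positive without mouse 1, at 0.267, or mouse 2, at 0.033. Salt-tolerant genera and Lactobacillus gave r = 0.407 (permutation p = 0.241, adjusted p = 0.481) and rho = 0.491 (permutation p = 0.156, adjusted p = 0.405), and r was 0.604 without mice 2 and 5.

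Reagent and water genera and depth gave r = 0.524 (permutation p = 0.117, adjusted p = 0.458) and rho = 0.782 (permutation p = 0.0102, adjusted p = 0.0817). Without mice 2 and 10, the farthest in depth, r was 0.80, and without mouse 10 alone rho was 0.95 (exact permutation p = 0.000353, adjusted p = 0.00282). The plan expected contamination to rise as depth falls, and these coefficients have the opposite sign. Library totals ran only from 22438 to 28578 reads and template was not measured, so the sign does not argue against contamination. The reagent share also split by mouse number. It was at most 0.314% in mice 2 to 5 and at least 0.380% in mice 6 to 10, with 1.41% in mouse 1. Depth tended to rise with number as well, so number and depth are not separated here. Plastid and mitochondrion share and depth gave r = 0.311 (permutation p = 0.364, adjusted p = 0.549) and rho = 0.442 (permutation p = 0.203, adjusted p = 0.405), with r = 0.545 without mice 2 and 10. Without mouse 2 alone, rho was 0.85 (exact permutation p = 0.00607, adjusted p = 0.0486). Depth and observed OTUs gave r = 0.196 (permutation p = 0.586, adjusted p = 0.586) and rho = 0.20 (permutation p = 0.581, adjusted p = 0.664), with r = 0.270 without mice 2 and 10. Depth and Shannon diversity gave r = -0.290 (permutation p = 0.415, adjusted p = 0.549) and rho = -0.236 (permutation p = 0.511, adjusted p = 0.664), with r = -0.0301 without them. None of the 8 relations passed the adjusted threshold over all 10 mice.

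A pair of Clostridia genera, and Klebsiella with Veillonella, varied together. Anaerotruncus and Butyricicoccus, a butyrate producer, gave rho = 0.939 (permutation p = 0.000200, adjusted p = 0.0465 over 465 pairs of 31 genera). Klebsiella, of the Enterobacteriaceae, and Veillonella, a lactate user, also gave rho = 0.939 (permutation p = 0.000180, adjusted p = 0.0465). These 2 were the only pairs called, both positive. Veillonella had reads in 8 mice, so its values in the others rest on the 0.5 added to 0 counts. Klebsiella and Veillonella both had their highest share in mouse 1. When any 1 of the 10 mice was left out, 0 pairs were called. A pseudocount of 1 also gave 0 pairs, shares in place of log ratios 8, Pearson's r 7 and a minimum share of 0.01% 1. At an unadjusted p under 0.05 there were 65 pairs, against a mean of 23.2 and a highest of 39 over 100 shuffles. The shuffles were centred on the 31 genera alone, while the log ratios were centred on unnamed groups as well. Shuffling each genus on its own also breaks any effect of a single mouse or of mouse number on many genera. The excess is therefore not by itself evidence of links between genera.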

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

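The comparison of each measure's extreme mouse with the others by Dixon's test was chosen before the data were examined, while all 3 tests of explanations for mouse 1, and the list of species they use, were chosen after its values were seen. With normally distributed values, chance sets a mouse apart in about 1 of 20 measures. Of 65 measures, 21 had a mouse set apart, where that rate gives 3.25, and 18 of the 21 were in mouse 1. Many shares are skewed, so 3.25 is not a tested chance value, and many measures overlap, since a genus also counts in its family and list.

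Mouse 1 had the highest share of several gut anaerobes. Bacteroides, and with it Bacteroidaceae, reached 5.36% (95% exact interval 5.09 to 5.64%), Prevotella 1.5% (1.36 to 1.66%) and the Bacteroidales list outside S24-7 7.5% (7.18 to 7.83%). Faecalibacterium reached 2.78% (2.58 to 2.99%). Bifidobacterium, and with it Bifidobacteriaceae, reached 3.80% (3.57 to 4.05%), the list of Bifidobacterium and Akkermansia 3.97% (3.73 to 4.22%) and the phylum Actinobacteria 4.08% (3.84 to 4.33%). OTU352, named Lactobacillus reuteri, reached 15.8% (15.3 to 16.2%). Other gut anaerobes were lowest in mouse 1, without being set apart by Dixon's test. Among them were S24-7 at 2.88% (2.68 to 3.10%), Lachnospiraceae at 3.63% (3.41 to 3.87%) and Oscillospira at 0.909% (0.796 to 1.03%). Clostridiales with no family name, to which the test was not applied, were also lowest there, at 3.87% (3.64 to 4.12%).

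Several environmental genera and the organelle reads were highest in mouse 1 as well. Ochrobactrum and its family Brucellaceae each reached 3.36% (3.14 to 3.59%), and the reagent and water genera together 1.41% (1.27 to 1.56%). Within that list Sphingomonas reached 0.278% (0.217 to 0.351%), Methylobacterium 0.204% (0.152 to 0.267%) and Comamonas 0.184% (0.135 to 0.245%). Stenotrophomonas, the most abundant genus of that list, was highest in mouse 7, at 0.517% (0.434 to 0.612%), and held 0.361% (0.291 to 0.442%) in mouse 1. Plastid and mitochondrion reads took 2.62% (2.43 to 2.82%) of its library, and its mean Bray-Curtis dissimilarity to the other mice was 0.694.

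Clostridiaceae reached 6.48% (6.17 to 6.81%) in mouse 4, Coprococcus 4.62% (4.35 to 4.90%) in mouse 3 and Streptococcus 0.609% (0.514 to 0.716%) in mouse 6. Plastid and mitochondrion OTUs, left out of the shares, held 1327 reads over the 10 libraries, above the limit that a count of 0 allows.

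In mouse 1, 12 species usual in the human gut or mouth, among them Faecalibacterium prausnitzii and Prevotella copri, summed to 6.00% of reads (95% exact interval 5.71 to 6.29%), against at most 1.78% (1.62 to 1.96%) in any other mouse, and 9 of the 12 were highest there. The list was written after the per-mouse counts were seen, so the high sum and the 9 of 12 follow at least in part from that choice. A low read total is argued against, since the library of mouse 1 ranked 9 of 10 from the smallest. A source with 1 fixed mix was tested by the chi-square of the 12 species over libraries. This chi-square was 11.2 per degree of freedom, and 7.18 without mouse 1. Both are above counting error, which argues against a mix of all 12 that varied by counting error alone. A mix with more dispersion, or of some of the species, stays open, since no technical replicate gives the dispersion of such reads. The closest 2 libraries differed by 12.3 over OTUs, but that value covers more reads and 2 different mice, so it is no yardstick. The criterion was changed repeatedly after values were seen. Less bacterial template, which would raise the share of any background DNA, may play a part but also stays open: the reagent and water genera together stood apart in mouse 1 (Dixon ratio 0.548), a value seen before the test was chosen, while only 4 of their 5 named genera were highest there, and template was not measured; no biological explanation was tested.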

How the results depend on the processing

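Merging OTUs was the 1 alternative chosen after the data were seen, and all others were chosen before. Of the alternatives, 743 kept direction and side of the threshold, stayed within 1.5 times a count or moved by less than the spread, with relations judged by rho alone. In 15 the sign turned, all of them differences or correlations not called, 13 lowered a count, 6 added a call or raised a count, and 1 moved a value by more than the spread. All 468 for single families and genera were among the 743, since they moved by less than 1 SD, although leaving out 1 mouse moved the means of 12 of these taxa by over 1.5 times. Leaving out 1 of 10 mice can never move a mean by 1 SD. For mean shares and mean Shannon diversity those settings could therefore not fail, and they say nothing on robustness. Settings for Bray-Curtis dissimilarity and for varying genera were judged against counting error, which separate mice exceed almost by construction. They could hardly fail either, so the 743 is not a measure of robustness. The 3 called within-mouse comparisons stayed called without any 1 mouse (adjusted p at most 0.0234). Leaving out mice one at a time gave Lactobacillus minus S24-7 -3.63 to 5.68 points, Lactobacillus minus Clostridia fermenters -3.33 to 4.17 and Clostridia fermenters minus S24-7 -0.872 to 3.59, none of them called. As a log2 ratio, Lactobacillus over Clostridia fermenters was -0.0706, and without OTUs under 10 reads Clostridia fermenters minus S24-7 was -0.103 points. Shannon diversity over genera was 2.27, as there are fewer genera than OTUs. Asking for 3 reads left 80 shared OTUs, and a minimum share of 0.01% gave 61 varying genera of 61 tested. Without the 2 mice farthest in depth or, for relations of Lactobacillus, in Lactobacillus, rho was 0.0714 for depth and Shannon diversity, 0.310 for Lactobacillus and S24-7, 0.381 for Lactobacillus and Clostridia fermenters and 1 for reagent genera and depth. Leaving out single mice gave rho of -0.233 to 0.267 for Lactobacillus and Clostridia fermenters, 0.70 to 0.95 for reagent genera and depth, and 0.267 to 0.85 for organelle share and depth, whose highest value, without mouse 2, was past the threshold (adjusted p = 0.0486). Called genus pairs numbered 0 with a pseudocount of 1, 8 on shares, 7 with Pearson's r, 1 of 903 with a minimum share of 0.01%, and 0 to 0 without single mice. The cause was not tested for any of these changes except the counts that follow from more or fewer taxa. Merging OTUs that tracked each other gave a Shannon diversity of 4.32, 155 shared OTUs and a Bray-Curtis dissimilarity of 0.544. Depth limits taxa below 0.0135% of a library.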

Other observations

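The tests of mouse number and of taxonomy strings were chosen after the patterns were seen, while those of depth and of chance agreement were written before their results were seen. The taxa named here were chosen after their values were seen. F16, a family of the candidate phylum TM7, whose members are small bacteria that live on other bacteria, reached 4.33% (95% exact interval 4.10 to 4.58%) in mouse 10 and 1.18% (1.05 to 1.32%) in mouse 9. Its mean was 0.673% ± 1.33 (SD, n = 10), or 0.266% without mouse 10. Lactobacillus reuteri held 5.53% ± 5.38 (SD, n = 10) of reads over all its OTUs, and [Ruminococcus] gnavus 3.21% ± 3.18 (SD, n = 10). Bacteroides acidifaciens, a mouse gut species, held 0.180% ± 0.0792 (SD, n = 10) and had reads in all 10 mice.

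Clostridiales OTUs without a family name differed by mouse. OTU3824 held 9.21% (8.84 to 9.59%) in mouse 3 and 0.0176% (0.00571 to 0.0411%) in mouse 10. Its share was at least 2.59% (2.39 to 2.80%) in mice 2 to 6 and at most 0.130% (0.0902 to 0.182%) in mice 7 to 10. In mouse 1 it was 0.717% (0.617 to 0.828%). Apart from mouse 1, its split thus followed the mouse numbers. OTU2433 held 6.70% (6.40 to 7.01%) in mouse 7 and had 0 reads in mouse 6, which allows up to 0.0125%. Akkermansia ran from 0.00383% (9.69e-05 to 0.0213%) in mouse 9 to 1.32% (1.18 to 1.47%) in mouse 3.

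Mice with near numbers had more similar communities, with a mean Bray-Curtis dissimilarity of 0.478 over the 9 neighbouring pairs and 0.594 over the 15 pairs at least 5 apart. The rank correlation of dissimilarity with difference in number was 0.339 (one-sided permutation p = 0.0173, n = 10 mice), and 0.359 without mouse 1 (exact one-sided permutation p = 0.0283). An unlabelled cage or processing batch that follows the numbers may explain this, but the labels do not say what the numbers stand for. The same test against difference in depth gave 0.218 (one-sided permutation p = 0.130), which is above 0 but not past the threshold, so depth stays open with 10 mice. Library totals also tended to rise with number, from 22438 reads in mouse 2 to 28578 in mouse 10, with mouse 1 at 26268. Number and depth are therefore not separated here. No biological explanation was tested.

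Some pairs of OTUs tracked each other over the mice. Among 76 OTUs with at least 500 reads, 18 of 2850 pairs had r of at least 0.95 on log shares, and 15 of the 18 shared a taxonomy string, against a mean of 1.60 and a highest of 10 over 10000 shuffles of the strings (permutation p = 0.0001, the smallest they can give). Chance is argued against, since 0 of 100 shuffles over mice gave as many pairs, with a highest of 1. The SD of their log2 ratio ran from 0.19 to 1.23, so not all kept a steady ratio. A candidate explanation for the tightest pairs is 1 organism counted in several OTUs, and closely related strains that vary together would give the same values. The shared strings are weak evidence for either, since none of them named a species. They ended at the genus for Lactobacillus pairs, at the family for S24-7 pairs and at the order for Clostridiales pairs. All the Lactobacillus pairs were among the same OTUs, which are named next. These OTUs were picked because they tracked each other, so steady proportions of their sum follow in part from that choice. Lactobacillus OTU1962, OTU678, OTU1690 and OTU1245 made up 54.9% ± 3.18, 28.0% ± 2.43, 14.2% ± 2.11 and 2.90% ± 0.762 (SD, n = 10 each) of their sum, while that sum ran from 0.363% to 32.6% of reads.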
